A study of Homo sapiens with 3 samples.

How the data were processed

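RNA from 3 cultures of the breast cancer cell line MDA-MB-231 was measured on 3 one-colour Agilent whole-genome expression arrays, 1 array for each stable line. One line carried a hairpin RNA against firefly luciferase (shLuc, the control) and the others carried hairpin RNAs against CD44 (shCD44-2 and shCD44-3). Per the labels' protocols, total RNA was column-purified and Cy3-labelled cRNA was made with a low-input amplification kit. Spot intensities were extracted by the authors with Agilent Feature Extraction 10.7.3.1, per the submitters' processing notes and the file headers. The deposited files hold, for each spot, a mean intensity, a local background intensity, a background-subtracted intensity and a processed intensity, all on a linear scale, with flags for spots that are not uniform, that are population outliers, that are saturated, or that are well above background. The authors also deposited a table of normalized signal values. For each of the 3 arrays, 100% of its values equalled the background-subtracted intensity, floored at 1, divided by the 75th percentile of the background-subtracted intensity over all spots, within a relative tolerance of 0.001. Its scale is therefore linear, it is not centred per gene, and its column medians were 0.105 for shLuc, 0.102 for shCD44-2 and 0.0999 for shCD44-3.

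The main values were computed here as the log2 of the processed intensity minus the array's 75th percentile of it, over spots that are neither controls nor outliers. That percentile was 1114 intensity units for shLuc, 1278 for shCD44-2 and 1238 for shCD44-3. Outlier flags removed 236, 289 and 181 of the 43118 non-control spots, and 0 spots were saturated. Spots of 1 probe were averaged on the log2 scale. A probe counted as measured on an array where most of its spots were well above background, which held for 69.0% of probes on shLuc, 70.1% on shCD44-2 and 68.1% on shCD44-3. Where 1 side of a comparison was not well above background, the difference was taken as a bound against the higher of the lowest log2 level among probes well above background on that array and the dim probe's own level. Such values are written "at least N-fold". Where both sides were dim, no difference was formed. The RefSeq table used for gene names, of assembly GRCh38.p14, matched 24826 probes by accession, 1188 by symbol and 472 by a unique synonym, and 7641 of the 34127 probes stayed without a gene and were left out of gene counts. The brightest of a gene's probes stood for it, giving 20039 genes, of which 5267 had more than 1 probe and 14438 were measured on all 3 arrays. Probe coordinates are those of the deposited files, on hg19. No genome sequence or gene model was used here, so exon and UTR positions are not given.

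With 1 array per group there are no replicates, so no p-value was computed and genes were called by size alone, at 2-fold or more. The only error that can be given is technical. On each array 999 probes are spotted 10 times, and those counted as measured had a median SD over spots of 0.0658 log2 units on shLuc (766 probes), 0.0656 on shCD44-2 (779) and 0.0567 on shCD44-3 (763). The other, dimmer probes were left out of these medians. By signal, the spot SD rose from 0.0562 for the brightest probes to 0.364 for the dimmest measured ones. A spot SD given beside a log2 change combines the values of both arrays at the gene's signal, is divided by the square root of the number of spots, and leaves out all variation between cultures, RNA preparations and arrays. The number of arrays limits the precision. All 3 arrays lie on 1 slide, so slide is the same for all groups and array position cannot be told apart from group. Of the spike-in control probes added at labelling, 8 were well above background on all arrays; relative to the 75th percentile their median was 0.30 log2 units higher on shCD44-2 and 0.15 higher on shCD44-3 than on shLuc. Changes are thus relative to the arrays' upper quartile, and levels set against the spike-in controls would be lower by those amounts.

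Gene lists (32 of them) and the rule for named genes were fixed before the data were examined. The median log2 change of a list's members measured on all 3 arrays was placed among 10000 random lists of the same size matched on mean signal in 20 bins, as a description of these arrays. A list stood apart where its percentile was under 2.5 or over 97.5 in both knockdown lines on the same side. Random lists treat genes as independent, which members of a pathway are not. Named genes were picked in several ways. Among genes measured on all 3 arrays, up to 12 per direction were taken that changed at least 2-fold the same way in both lines. These were ranked by the smaller change. Also among measured genes, up to 6 per direction and line changed at least 2-fold in it and under 1.41-fold in the other. Up to 6 measured genes changed 2-fold in opposite directions. Up to 5 per direction reached 2-fold in both lines through a bound, taken by brightness. From each list came up to 4 members with the largest mean absolute change of the 2 lines. That measure also picks genes that moved in opposite directions. Genes whose name in the files is an accession, clone, LOC or open reading frame number were not named. CD44, HAS1, HAS2 and HAS3 were named in any case. A gene that the rule selects is not reported here.

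Because both knockdown lines were set against the same control array, shared counts were placed beside the overlap of independent lists, beside the same count with each other array in the control's place, and beside 100 simulated sets of 3 unchanged arrays with the spread of the replicate spots. On simulated arrays of 14435 genes for shCD44-2 against shLuc, the 2-fold rule called 97 of 100 genes changed 3-fold, 1 of 100 changed 1.5-fold and 10 of 14235 unchanged ones. For shCD44-3 against shLuc it called 96, 0 and 9. The simulated arrays held spot noise alone, and none of their genes was called through a bound. These rates therefore leave out variation between cultures, RNA preparations and arrays, and are not the error rates of the real comparisons. Of 200 simulated random lists, 6.0% lay outside the percentiles in shCD44-2 and 3.0% in shCD44-3.

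The alternatives were quantile normalization of the processed intensities, scaling to the median, normexp background correction of the mean and background intensities (offset 50) with quantile normalization, the authors' table, the median over a gene's probes, outlier spots kept, both-sided measurement only, no filter on dim probes, and rules of 1.5-fold and 3-fold. Added after seeing the data were changes set against the median change of the spike-in controls, a correction for the probes' GC content (10 bins) and signal (20 bins) and a restriction to genes with a mean normalized log2 signal above -4. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used.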

Results

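Gene expression was measured in MDA-MB-231, a human breast cancer cell line of basal, mesenchymal character that is widely used in studies of metastasis, after stable knockdown of CD44 with either of 2 hairpin RNAs. CD44 is a cell-surface receptor for hyaluronan, a polysaccharide of the extracellular matrix. Each of the lines shLuc, shCD44-2 and shCD44-3 was hybridised to 1 array, so no difference below has a replicate check. Differences are log2 changes of normalized signal, and the spot SD beside a value is that expected of the difference of 2 arrays from the spread between spots, divided by the square root of the number of spots of the probe.

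CD44 was the first gene examined, because it shows whether the labels hold. Its single probe (NM_000610, hg19 chromosome 11, 35253812 to 35253871) stood 4.99 log2 units above the array's 75th percentile in shLuc, against 1.19 in shCD44-2 and 1.35 in shCD44-3. CD44 mRNA was thus 13.9-fold lower in shCD44-2 (log2 change -3.80, spot SD 0.079) and 12.5-fold lower in shCD44-3 (-3.64, spot SD 0.079), which leaves 7.17% and 8.02% of the control's signal. The 2 knockdown lines differed from each other by 0.16 log2 units at CD44. Both knockdown arrays remained well above background for CD44.

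The next question was whether the enzymes that make the ligand of CD44 changed with it. HAS2, a hyaluronan synthase, was 3.60-fold lower in shCD44-2 (log2 change -1.85, spot SD 0.086) and 2.69-fold lower in shCD44-3 (-1.43, spot SD 0.061). These SDs are small because they are for means of 10 spots. Its probe (hg19 chromosome 8, 122626087 to 122626146) is spotted 10 times on each array, and over those 10 spots the log2 level was -3.33 ± 0.12 (SD) in shLuc, -5.18 ± 0.20 in shCD44-2 and -4.76 ± 0.21 in shCD44-3. HAS1 and HAS3 did not reach 2-fold in either line. HAS1, with 1 of its 3 probes above background, gave -0.55 and -0.31, and HAS3 gave -0.27 and -0.19. Under normexp correction, which pulls dim signals together, HAS2 no longer reached 2-fold in either line (-0.84 and -0.71).

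Beyond HAS2, the list of hyaluronan genes (synthases, hyaluronidases, binding proteins) had a median log2 change of -0.12 in shCD44-2 and -0.19 in shCD44-3 over 13 measured members, at percentiles 8.61 and 1.65 of random lists, so it did not stand apart in both lines; 5 of 8 alternatives brought shCD44-3 within the random lists. HAS2 was its 1 member that passed 2-fold in both. Other members with large changes were HAPLN3 (0.32 and -0.73), CEMIP (-0.46 and -0.43) and HMMR (-0.31 and -0.58). Among CD44 partners, with medians of -0.05 and 0.04, CD74 gave -1.38 in shCD44-2 and -0.67 in shCD44-3. SPP1, which encodes the CD44 ligand osteopontin, was at least 2.44-fold higher in shCD44-3, where it was measured, than in shLuc.

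Both hairpins were then compared for what they had in common. In both knockdown lines 49 genes were at least 2-fold lower than in shLuc and 8 were at least 2-fold higher, out of 14993 genes compared in both. These counts depend on the processing, with 99 lower and 2 higher against the spike-in controls and 9 lower and 1 higher under normexp correction. After CD44, and among genes measured on all 3 arrays, those that fell most in both lines, ranked by the smaller of the 2 changes, were IFITM1, an interferon-induced membrane protein that restricts virus entry (19.3-fold and 11.6-fold lower, hg19 chromosome 11, 315209 to 315268), and GMFG, a regulator of branched actin (11.4-fold and 5.82-fold lower, chromosome 19, 39819087 to 39819146). LCP1, the actin-bundling protein L-plastin, rose most among genes measured on all 3 arrays, ranked by the smaller of the 2 changes, by 7.42-fold in shCD44-2 and 4.04-fold in shCD44-3 (chromosome 13, 46700337 to 46700396). These 3 genes had spot SDs of at most 0.17 log2 units in either line.

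**Figure D1:**
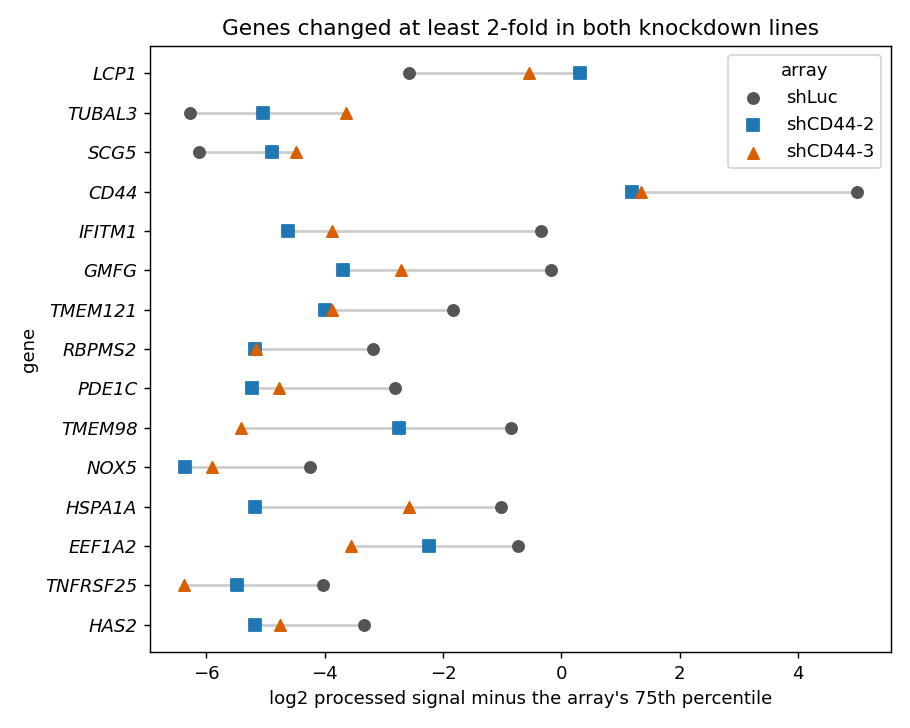
Normalized log2 signal (x axis, log2 processed signal minus the array's 75th percentile) of the 15 named genes changed at least 2-fold the same way in both knockdown lines (y axis), with 1 point per array and a grey line spanning the 3 arrays. CD44 drops from 4.99 in shLuc to 1.19 and 1.35, and LCP1 goes from -2.57 to 0.32 in shCD44-2 and -0.55 in shCD44-3.

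Further genes lower in both lines included TMEM121 (log2 change -2.17 in shCD44-2 and -2.06 in shCD44-3), RBPMS2 (-1.99 and -1.98), the phosphodiesterase PDE1C (-2.42 and -1.96), the NADPH oxidase NOX5 (-2.11 and -1.66) and the death receptor TNFRSF25 (-1.44 and -2.35). TMEM98 fell by 1.88 in shCD44-2 and by 4.56 in shCD44-3, and the translation elongation factor EEF1A2 fell by 1.51 and by 2.83. HSPA1A, an inducible HSP70 gene, gave -4.16 in shCD44-2 and -1.56 in shCD44-3, whereas the probe of its near-identical neighbour HSPA1B, looked up after the values were seen, gave 0.25 and -0.02, so the probes of this gene pair disagreed. Besides LCP1, TUBAL3 (1.24 and 2.63) and SCG5 (1.23 and 1.64) were higher in both, at signals near the floor in shLuc. Under normexp correction 6 of these genes no longer reached 2-fold in both lines. RBPMS2 (-0.997 and -0.90), NOX5 (-0.73 and -0.62), TNFRSF25 (-0.54 and -0.72) and SCG5 (0.30 and 0.44) fell short in each line. PDE1C fell short in shCD44-3 alone (-0.95) and TUBAL3 in shCD44-2 alone (0.42). Genes that were not well above background on 1 side add bounds. The inflammasome gene NLRP2 was at least 18.8-fold lower in shCD44-2 and at least 15.3-fold lower in shCD44-3, EFS at least 7.45-fold and 6.28-fold lower, and GLUL, glutamine synthetase, at least 6.09-fold and 4.96-fold lower by its single probe. LEFTY1 (3.34-fold lower in shCD44-2, at least 4.84-fold lower in shCD44-3) and DMRT2 (3.01-fold lower, at least 4.49-fold lower) followed. In the other direction, ADAMTS3 was at least 3.74-fold and 4.82-fold higher, NR4A3 at least 2.15-fold and 3.42-fold, and CIDEB at least 2.11-fold and 2.06-fold. Of these 8 genes only NLRP2 kept 2-fold in both lines under normexp correction. For ADAMTS3, NR4A3 and CIDEB the spot SDs were 0.40 to 0.44 log2 units. The CIDEB bounds (1.08 and 1.04 log2 units) and the NR4A3 bound in shCD44-2 (1.11) passed 2-fold by less than their spot SD.

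Independent lists of these sizes would share 2.35 lower genes and 0.40 higher ones. Among genes measured on all 3 arrays, 35 were shared, and unchanged arrays simulated with spot noise shared at most 6 in 100 sets. That simulation leaves out variation between cultures, RNA preparations and arrays, so it does not show that the 35 are more than such variation gives. The same count with another array in the control's place was larger. The shLuc array stood at least 2-fold apart from both other arrays at 57 genes, shCD44-2 at 130 and shCD44-3 at 184. Across the 14438 genes measured on all arrays, which are not independent replicates, the log2 changes of the 2 hairpins correlated with Pearson r = 0.26 and Spearman rho = 0.26. Simulated unchanged arrays that share the control gave a mean r of 0.50. Sharing a control gives about that value to unchanged arrays of equal noise, whatever the size of the noise. The observed r is thus no sign of agreement by itself, and this comparison neither shows nor excludes agreement between the hairpins. Their covariance was 0.0262, against 0.0113 for simulated unchanged arrays that share the control. With a single control array the control cannot be split, so part of the shared changes may come from shLuc itself.

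Of the 32 gene lists, 3 stood below random lists in both knockdown lines and 0 stood above them in both. Random lists of the same sizes would give 0.11 lists on the same side. That value is too low a yardstick, because 11 of the 32 lists lay outside the percentiles in shCD44-2 and 16 in shCD44-3. Another 3 lists lay outside them on opposite sides. The shared lists thus do not show agreement between the hairpins. Mitosis genes, such as kinases and motor proteins of the spindle, were 1 of the 3 lists lower in both. Their median was -0.16 in shCD44-2 and -0.10 in shCD44-3, lower than all 10000 random lists in both lines, with 7 and 5 of its 33 members above 0 and 0 members past 2-fold. CCNA2 (-0.44 and -0.32), PLK1 (-0.54 and -0.20) and CENPE (-0.40 and -0.25) were among its largest values. Cytokine genes had medians of -0.18 and -0.14 over 28 measured members (percentiles 0.06 and 1.12). The members did not move together, since CSF3 gave -1.50 and -0.57 and IL24 gave 0.86 and 1.73, and CCL2 was at least 3.61-fold lower in shCD44-2 but 0.17 in shCD44-3. Genes of luminal breast epithelium had medians of -0.26 and -0.14 over 17 members (percentiles 0.01 and 2.13), with KRT19 at -3.08 and -0.80, TFF3 at -0.65 and -3.12, AGR2 at -1.05 and -0.73 and CA12 at -0.72 and -0.10. In shCD44-3 the cytokine list lost its place under 2 of 8 alternatives and the luminal list under 4 of 8.

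**Figure D2:**
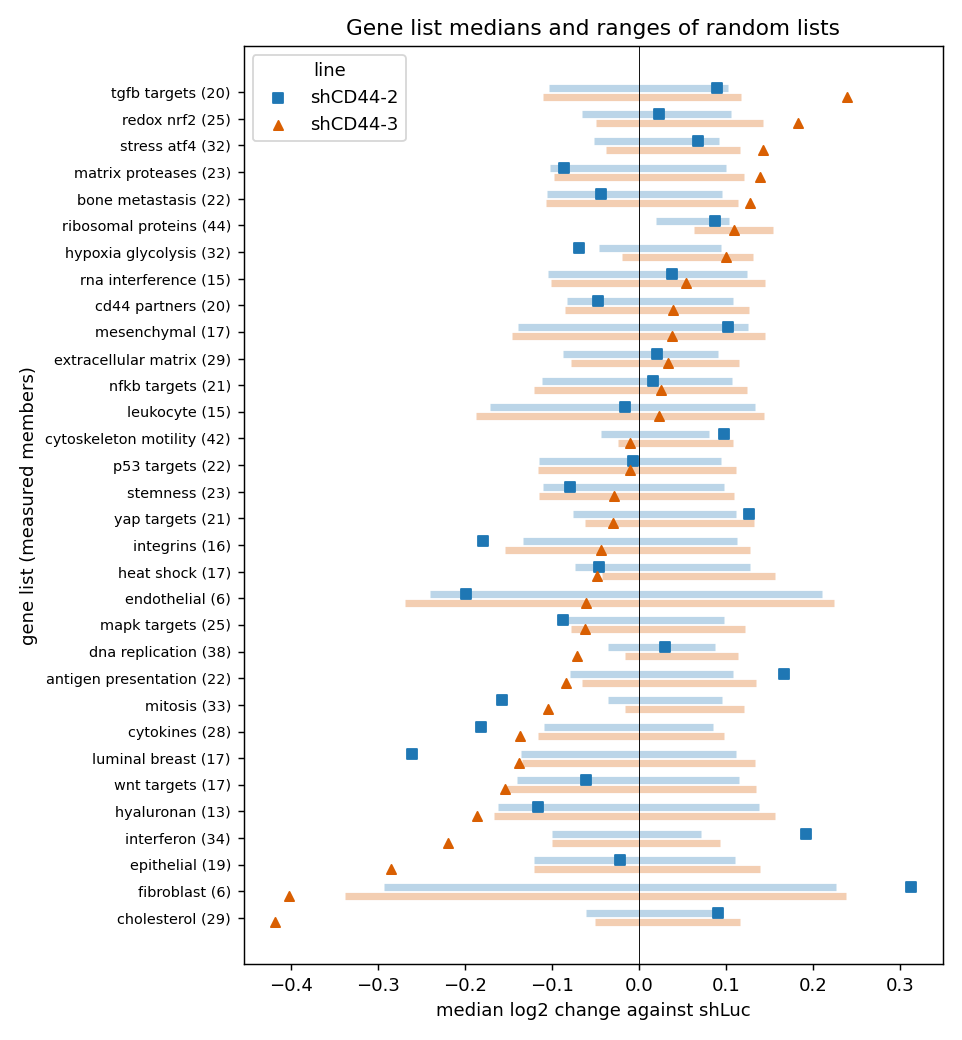
Median log2 change against shLuc (x axis) of each gene list (y axis, with the number of members measured on all 3 arrays) in shCD44-2 (squares) and shCD44-3 (triangles). Pale bars span 10000 random lists matched on signal, without the outermost 2.5% at either end. The mitosis medians of -0.16 and -0.10 lie left of both bars, while the interferon medians of 0.19 and -0.22 lie on opposite sides.

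In shCD44-2 compared with shLuc, 136 genes were at least 2-fold higher and 132 at least 2-fold lower, 1.76% of the 15260 genes compared. This balance depends on the scaling, since against the spike-in controls 71 were higher and 367 lower. Genes higher in this line and little changed in the other included the matricellular protein CCN3 (log2 change 2.08, spot SD 0.10), the collagen COL12A1 (1.83), ATF7IP2 (1.74), LRATD2 (1.62), RIMS2 (1.58) and the cytokine IL7 (1.56). Those lower included PICK1 (-3.22, spot SD 0.10), the stress-responsive cytokine GDF15 (-2.21), GGTLC1 (-2.15), CACNG6 (-1.80) and the olfactory receptor pseudogenes OR7E13P (-1.52) and OR7E104P (-1.46), which belong to a family of similar copies. Under normexp correction ATF7IP2 (0.67), LRATD2 (0.96) and CACNG6 (-0.79) no longer reached 2-fold. List medians beyond the percentiles in this line and not in the other were those of YAP targets (0.13, percentile 98.7, within the random lists under 3 of 8 alternatives), cytoskeleton and motility genes (0.10, percentile 99.4, within them under 1 of 8), integrins (-0.18, percentile 0.51), hypoxia and glycolysis genes (-0.07, percentile 0.53) and MAPK targets (-0.09, percentile 1.88, within them under 2 of 8). Set against the spike-in controls, the YAP and cytoskeleton medians turned to -0.17 and -0.20. Whether these lists differed between the lines was not tested. Among integrins ITGA2 gave -1.27 and ITGB4 -0.87 (-1.99 in shCD44-3), and among YAP targets CCN2 gave -0.97 against the direction of its list.

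In shCD44-3 compared with shLuc, decreases outnumbered increases, with 267 genes at least 2-fold lower and 65 at least 2-fold higher, 2.20% of the 15073 genes compared. The gluconeogenic enzyme FBP1 was 30.0-fold lower (log2 change -4.91, spot SD 0.17), the neurotrophin receptor NGFR 13.7-fold lower (-3.77), DMBT1 9.23-fold lower and PLBD1 9.08-fold lower, all with little change in shCD44-2. RASSF2 (-2.38) and CDON (-2.19) followed. SERPINB2, an inhibitor of plasminogen activators, rose by 3.58 on the log2 scale (spot SD 0.26) and the neural transcription factor POU3F2 7.77-fold higher (2.96), followed by PTPN22 (1.88), ST8SIA4 (1.57), SNCAIP (1.44) and the glycolytic enzyme ALDOC (1.37). Under normexp correction CDON (-0.91), PTPN22 (0.92), ST8SIA4 (0.81) and SNCAIP (0.81) no longer reached 2-fold.

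Cholesterol synthesis genes had a median of -0.42 in shCD44-3 over 29 measured members (percentile 0), with 3 of its members above 0. SC5D fell by 1.26 and SCD by 1.24 on the log2 scale. In shCD44-2 the median of that list was 0.09. Epithelial genes had a median of -0.29 in shCD44-3 (percentile 0.01) against -0.02 in shCD44-2, with SPINT1 at least 4.09-fold lower in shCD44-3. DNA replication genes had medians of -0.07 in shCD44-3 (percentile 0.05) and 0.03 in shCD44-2, and RRM2 gave -0.42 and -0.33. On the other side, TGF-beta targets had a median of 0.24 in shCD44-3 (percentile 100) and 0.09 in shCD44-2, with ID2 at 1.70 and 0.99, SMAD7 at 0.77 and 0.64, ID3 at 0.98 and 0.32 and CCN2 at -0.45 and -0.97. Of its 20 measured members, 13 lay above 0 in shCD44-3 and 11 in shCD44-2. Genes of the NRF2 response (0.18, percentile 99.8, with HMOX1 at 1.12), of the ATF4 stress response (0.14, percentile 99.6, within them under 2 of 8, with DDIT3 at 0.69), matrix proteases (0.14, percentile 99.0, with MMP3 higher by a bound of 3.58 log2 units) and genes linked to bone metastasis (0.13, percentile 98.7, within the random lists under 3 of 8 alternatives) had medians above the random lists in shCD44-3. Set against the spike-in controls, those of ATF4, proteases and bone metastasis turned to -0.011, -0.015 and -0.026. Heat shock genes had a median of -0.05 in both lines (percentile 2.06 in shCD44-3), and scaling to the median turned the sign in shCD44-3. Under 6 of 8 alternatives the list lay within the random lists there.

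The hairpin lines were finally compared with each other. They differed at least 2-fold at 469 genes, of which 341 were lower in shCD44-3 and 128 higher, more than either line differed from shLuc. Several of these genes belong to the mesenchymal and metastasis lists. CDH11, a mesenchymal cadherin, was 1.85 log2 units higher than shLuc in shCD44-2 and at least 24.0-fold lower in shCD44-3. WNT5A gave 1.04 and -3.53, and the chemokine receptor CXCR4 was 5.66-fold higher in shCD44-2 and at least 3.58-fold lower in shCD44-3. SPP1, of the bone metastasis list, went the other way and was at least 2.69-fold higher in shCD44-3 than in shCD44-2. The medians in shCD44-2 and shCD44-3 were 0.10 and 0.04 for mesenchymal genes and -0.04 and 0.13 for bone metastasis genes. The members named here thus do not stand for their lists. The desmosomal protein DSP, of the epithelial list, gave 2.23 and -2.90. The surface marker CD24, of the stemness list, gave 2.36 and -0.70. Altogether 26 genes passed 2-fold in opposite directions, 25 of them higher in shCD44-2 and lower in shCD44-3.

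**Figure D3:**
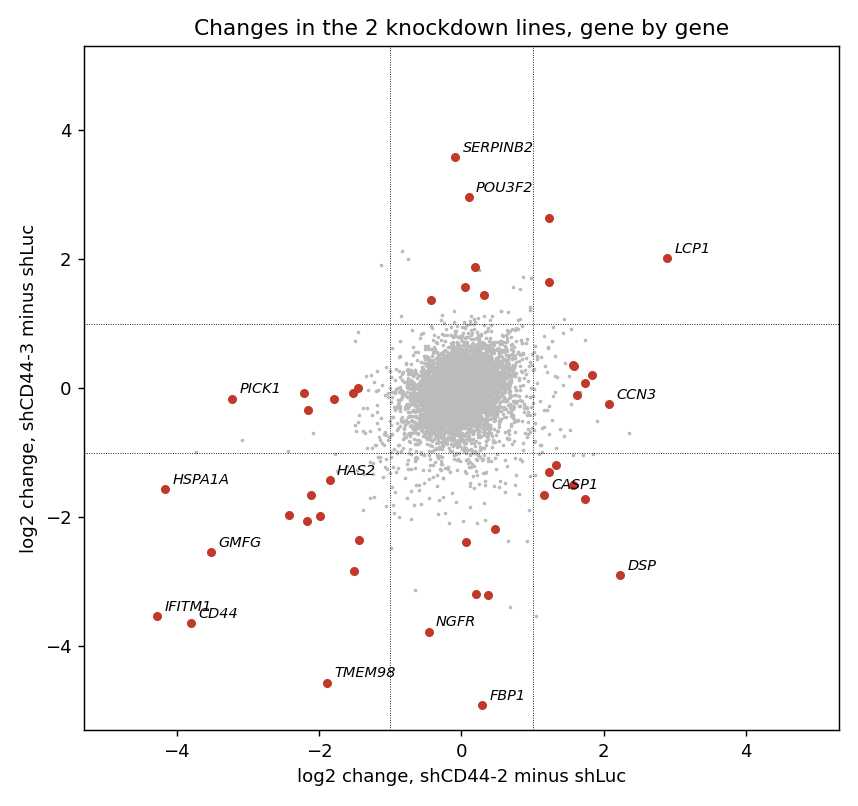
Log2 change of each gene measured on all 3 arrays in shCD44-2 (x axis) and in shCD44-3 (y axis), both against shLuc, with the named genes in red and dotted lines at 2-fold. CD44 lies at -3.80 and -3.64 at the lower left, FBP1 at 0.30 and -4.91 at the bottom, and DSP at 2.23 and -2.90 at the lower right.

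Interferon-response genes had a median of 0.19 in shCD44-2 (percentile 100) and -0.22 in shCD44-3 (percentile 0.01) over 34 members. In shCD44-2, 24 members lay above 0, and in shCD44-3, 7 did. MX1 gave 0.22 and -2.10, OAS1 gave 1.49 in shCD44-2, and IFI44L went the other way, with -0.56 and 0.84. IFITM1 belongs to this list and fell in both lines. Antigen presentation genes had medians of 0.17 and -0.08 (percentiles 99.9 and 1.20), although CIITA gave -1.16 and -0.64 and HLA-DMA -0.69 and -0.25. Set against the spike-in controls, both lists were lower in both lines, with -0.11 and -0.37 for interferon genes and -0.13 and -0.24 for antigen presentation genes. Markers of other cell types were examined because a line could hold other cells. Fibroblast markers had medians of 0.31 and -0.40 over 6 measured members, and PDGFRB gave 0.20 and -1.10, whereas ACTA2 gave -0.73 and -1.01. The list lay within the random lists in shCD44-2 under 1 of 8 alternatives. Endothelial markers had medians of -0.20 and -0.06 and leukocyte markers of -0.02 and 0.02, with LCP1 the 1 leukocyte gene past 2-fold in both lines and PTPRC at -0.45 and -0.49.

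The remaining lists lay within the percentiles in both lines. Medians in shCD44-2 and shCD44-3 were 0.02 and 0.03 for extracellular matrix genes, where COL6A2 gave -0.35 and -1.04, and 0.10 and 0.04 for mesenchymal genes. They were -0.08 and -0.03 for stemness genes, where NES gave -1.28 and -0.66, and 0.02 and 0.03 for NF-kB targets, where ICAM1 gave -0.35 and -1.35. Wnt targets had medians of -0.06 and -0.15, p53 targets of -0.01 and -0.01, ribosomal protein genes of 0.09 and 0.11, and RNA interference genes of 0.04 and 0.05.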

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

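The comparison of shLuc with each other array and the tests of other scalings, spike-in scaling included, were chosen after the result was seen. The 2 knockdown lines moved in opposite directions from shLuc at the genes and lists given here. With 1 array per line, these differences were not tested. Log2 changes in shCD44-2 and shCD44-3 were 2.23 and -2.90 for DSP, 1.73 and -1.71 for OLFML3, 1.56 and -1.49 for ATP6V0A4, 1.23 and -1.31 for ARRDC4, 1.33 and -1.19 for CELF4, and 1.16 and -1.65 for CASP1. Under normexp correction only DSP of these 6 kept 2-fold in both lines. There OLFML3 gave 1.32 and -0.64, ATP6V0A4 1.26 and -0.79, ARRDC4 0.96 and -0.59, CELF4 0.90 and -0.54 and CASP1 0.90 and -0.97. List medians were 0.17 and -0.084 for antigen presentation, 0.31 and -0.40 for fibroblast markers, and 0.19 and -0.22 for interferon genes. Set against the spike-in controls these became -0.13 and -0.24, 0.012 and -0.55, and -0.11 and -0.37. The opposite directions of interferon and antigen presentation genes thus hold only relative to the other genes of each array.

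The interferon list differed between the 2 lines by a median of -0.54 log2 units over its 34 measured members (shCD44-3 minus shCD44-2). After the median change of probes of like GC content and signal was removed, the difference was -0.56, which argues against these probe trends as the whole cause. Quantile normalization, median scaling and the authors' table gave -0.54, -0.54 and -0.55. Normexp with quantile normalization gave -0.40, under the bound set for excluding the scaling. That setting changes the background correction as well, so the 2 cannot be told apart, and processing stays open as a part of the size. Median scaling, the authors' table and the spike-in controls (-0.40) each scale all genes of an array by 1 amount, so they decide nothing here. A candidate explanation is that the 2 stable lines differ in interferon tone, through the hairpin sequence or through the cells each line grew from. The design has 1 line per hairpin, and this was not tested.

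The 57 genes changed the same way in both lines are the ones a reader would assign to CD44. After the correction for GC content and signal, 56 of the 57 still changed at least 2-fold in both, so those trends do not account for them. A state of the shLuc line or array alone stays open. shLuc stood apart from both other arrays at 57 genes, while shCD44-3 stood apart at 184, so a single line can differ from the rest by more genes than the pattern holds. Knockdown and control state cannot be told apart for these genes, CD44 aside, because there is 1 control array.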

How the results depend on the processing

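CD44 log2 changes stayed between -3.85 and -3.76 in shCD44-2 under all alternatives but the spike-in controls (-4.10); in shCD44-3 quantile normalization gave -3.73 and the spike-in controls -3.79, beyond 1 spot SD. The counts stayed within 1.5 times under quantile normalization of processed signals, median scaling, the authors' table, probe medians, kept outlier spots and the GC and signal correction. Below, counts run in this order: higher and lower in shCD44-2, higher and lower in shCD44-3, higher and lower in both, and apart between the lines. Normexp with quantile normalization gave 33, 36, 19, 65, 1, 9 and 168, and 8 of the 15 genes named for both lines stayed past 2-fold. No filter on dim probes gave 536, 593, 406, 744, 117, 243 and 1350. A mean signal above -4, chosen after seeing the data, gave 45, 48, 22, 128, 2, 11 and 242. Set against the spike-in controls, also chosen after seeing the data, they were 71, 367, 40, 376, 2, 99 and 482. The 1.5-fold rule gave 496, 539, 344, 823, 71, 194 and 1520, and the 3-fold rule 32, 33, 19, 84, 2, 14 and 166. Both sides well above background gave 41 higher in shCD44-3, 4 higher in both and 31 lower in both. The fold rules, the signal limit and the filters on dim probes change the counts by construction. So does normexp in part. Its offset of 50 intensity units exceeds the lowest measured signals of 10.9 to 13.6 units, which shrinks the log2 changes of dim genes. What else normexp changes, and the cause of the shifts at CD44, were not tested. The correlation ranged from 0.24 to 0.27, and 2 to 4 lists stood apart. The heat shock median in shCD44-3 turned to 0.0027 with median scaling. The spike-in controls turned the medians of antigen presentation (-0.13), cytoskeleton (-0.20), interferon (-0.11) and YAP (-0.17) genes in shCD44-2, and of bone metastasis (-0.026), protease (-0.015) and ATF4 (-0.011) genes in shCD44-3; places among random lists cannot change there. Of 53 changes scored, 1 per named gene, none turned its sign, while 391 checks were the same and 33 weaker. Small changes in the other line could turn. SERPINB2 in shCD44-2 went from -0.086 to 0.11 under normexp correction. Most of the genes changed in both lines lie at low signal. No paired analysis was possible because each group has 1 array.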

Other observations

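The test of signal gains was chosen after the values were seen. Histone H2B genes, which are in none of the fixed lists and were picked after their values were seen, were mostly higher in both knockdown lines. Over 16 measured H2B genes the median log2 change was 0.52 in shCD44-2 and 0.72 in shCD44-3, and 14 of 16 lay above 0 in each line. Both changes are set against the same shLuc array, so the 2 lines are not independent observations. A state of the shLuc line or array alone stays open for these genes too. H2BC12 gave 0.96 and 1.25, H2BC10 gave 0.72 and 0.91, and H2BC6 gave -0.45 and -0.35. H3 genes had medians of -0.04 and -0.00051 over 12 genes, H4 genes of -0.07 and 0.01 over 13 and H2A genes of 0.07 and 0.14 over 15. H1 genes had medians of 0.13 and 0.47, with 3 of 3 higher in both lines and H1-2 at 0.37 and 0.93. The H2B medians were above 0 under all 8 alternatives, from 0.46 to 0.57 in shCD44-2 but for 0.22 against the spike-in controls.

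A rise of all histone mRNAs, as labelling or tail addition at all of them would give, is argued against by the other histone genes. Their median change was at most 0.070 of the H2B median in either line. That pooled median rests mostly on the H2A, H3 and H4 genes, and a rise shared by H2B and H1 genes stays open. Labelling or tail addition confined to some histone genes stays open too, because it need not raise the others. An equal reading of 1 transcript by all H2B probes is argued against too, since the SD of the H2B changes was at least 3.81 times the spot SD. That bound leaves out a reading in part, in which similar copies dilute 1 transcript to different degrees. In that case the gains in linear signal would keep 1 ratio between the lines. The ratio of gains, shCD44-3 over shCD44-2, had a median of 1.43 over 14 genes. Its log2 SD of 0.33 lay between the bounds of 0.25 and 0.5 set for this test. The highest and lowest ratios were those of H2BC21 and H2BC15. Their log2 changes in shCD44-2 were small, at 0.17 (spot SD 0.12) and 0.13 (spot SD 0.086). Spot noise may thus make up part of that SD, and the test does not decide whether 1 transcript was read in part. The number of H2B genes that changed may therefore be smaller than the number of probes.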
